A study of Mus musculus with 20 samples.

How the data were processed

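Dermal fibroblasts of female mice were measured on 1 array per mouse, 20 arrays in 4 groups of 5. Per the labels, skin was freed of its subdermis and digested with collagenase, and the sort kept cells that carried Pdgfra and CD34 on their surface and lacked EpCAM, CD31, CD24, CD117 and CD45. RNA of 10000 sorted cells was isolated with magnetic beads, amplified over 20 cycles, and 8 µg of labelled cDNA was hybridized to an Affymetrix mouse array. Mice from different groups were collected on the same day per the labels, and the day was not used here.

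The deposited values are log2 expression levels per probe set, made by the authors with RMA from the affy package (background correction, quantile normalization over arrays and median polish), whose versions are not given. They have 2 decimals and lie between 2.71 and 13.46, and no further filter or batch correction is stated. An array has no read depth, and the number of arrays limits the precision. Of 45141 probe sets, 28898 name 1 gene in the annotation used, 551 name several and 15692 name none, and the last 2 classes were left out. Symbols were brought up to date against a RefSeq table of the GRCm38.p6 assembly through Entrez numbers, which matched 28689 probe sets. For each of 17097 genes the probe set with the highest mean over all 20 arrays was kept. No dim gene was left out.

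Groups were taken from the labels. All 20 arrays were fitted together with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 1 mean per group, no covariate, 16 residual and 4.19 prior degrees of freedom. Each comparison was tested two-sided with limma's moderated test, and p was adjusted by Benjamini-Hochberg over the 17097 genes, with a threshold of 0.05. The comparisons were Old ND with Young ND, Old CR and Old CR-ND each with Old ND and with Young ND, and Old CR-ND with Old CR. Standard errors are those of limma, and SD values are over the 5 arrays of a group.

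Gene lists for 33 pathways and 19 cell types were written before the data were examined, as were the comparisons, the tests, the alternatives and the rule for naming genes. A list was tested when at least 5 of its genes were measured, with camera at a preset correlation of 0.01, and p was adjusted over the lists of its kind within a comparison. Camera with a correlation estimated per list and fry were run beside it. Camera compares a list with the other genes, and fry asks whether its genes move on balance in 1 direction. The counts adjusted over the list alone use Benjamini-Hochberg over the members of that list.

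The rule for naming genes covered the 3 comparisons with Old ND as 1 side and Young ND, Old CR or Old CR-ND as the other. It took the 8 largest rises and the 8 largest falls among genes past the threshold whose higher group mean lay above the median gene level, without predicted or clone symbols and without near-identical families that the array cannot tell apart. The families were listed by hand after the data were seen, which set aside Ctla2a and Csprs. Where none passed in a direction it took the 3 genes with the smallest p. From each list it took up to 4 members past the threshold with the smallest adjusted p, or up to 2 members where none passed. The sorting markers, the genes sorted against and a small set of collagen, fat cell and cell cycle genes were always eligible. Genes named outside the rule are marked as chosen after their values were seen.

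The age score of an array is its position on the line from the mean of Young ND to the mean of the 15 old arrays over the 200 genes with the smallest p for all old against Young ND. Scores were compared by exact permutation tests, two-sided, with Benjamini-Hochberg over the 3 tests. The correlation across genes of the age effect with each restriction effect shares the Old ND arrays, so it and the covariance were set beside 1000 simulated data sets with no effect and beside the mean over 20 ways to split the Old ND arrays between the effects.

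The array numbers form 2 separate runs, and values within each run and with the run as a block in limma are given. The lone Old CR array of the second run was assumed to vary like the other groups. The alternatives were filters on dim genes, every probe set or the mean of a gene's probe sets, quantile normalization once more, centring on the array median, eBayes with trend and robust, array weights, only the 2 groups compared, the runs, each array left out in turn, and other thresholds. Leaving out arrays was added after the data were seen for the genes of Old CR-ND against Old CR, for Ctla2a and Csprs, for cell type lists, and for calls with an estimated correlation.

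The pipeline was tested on simulated data with the same group sizes and 17097 genes. For Old CR against Old ND it called 73.0% of 74 genes changed by 0.5 on the log2 scale, 98.4% of 64 genes changed by 1 and all of 62 genes changed by 2, and 14 of 16897 unchanged genes. It called 3 of 3 shifted lists and 1 of 30 others, and 0 genes in a comparison with no simulated change. Each gene was drawn independently of the others and without a run effect. The check therefore does not cover false calls that arise from correlated genes or from the run.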

Results

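RNA from fibroblasts sorted out of the dermis of female mice was measured on 20 arrays, 5 mice in each of 4 groups. Young ND mice were 4 weeks old per the labels and ate a normal diet (ND) for 4 weeks, which leaves their age at collection open. The other 15 mice entered the study at 9 months of age and were collected at 18 months. Old ND mice ate the normal diet throughout, Old CR mice ate it for 2 months and were then held on 30% caloric restriction (CR) for 7 months, and Old CR-ND mice had the 7 months of restriction first and the normal diet for the last 2 months. All values below are log2 array levels, differences are log2 fold changes ± the standard error from limma with n = 5 arrays per group, and each adjusted p is over the 17097 genes tested. The number of arrays limits the precision, with a median standard error of 0.10. The median level per array lay between 5.27 and 5.34, and no pair of arrays carried the same values. The first 4 principal components held 26.9%, 17.2%, 13.0% and 10.1% of the variance. The array numbers fall into 2 separate runs, 13 arrays in the first run and 7 in the second, and 2934 genes differed between the runs with the groups held constant. Young ND, Old ND and Old CR-ND each had 3 arrays in the first run and 2 in the second, and Old CR had 4 and 1, so values within runs are given beside the main ones.

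The comparison of Old ND with Young ND asks what differed with age on a normal diet. Bcat1, the cytosolic enzyme that starts the breakdown of branched-chain amino acids, had the largest change on the brightest probe set and fell by 4.02 ± 0.13 (16.2-fold, adjusted p = 2.28e-14), from 8.15 ± 0.38 (SD) in Young ND to 4.13 ± 0.13 in Old ND. The Old ND level lay near the lower quartile of the arrays (4.11 to 4.25), where background compresses the scale, and with the mean of its probe sets Bcat1 changed by -2.45 (5.45-fold). The noncoding RNAs Mirg (-3.28 ± 0.31), Rian (-2.50 ± 0.13) and Meg3 (-2.38 ± 0.20) of 1 imprinted locus fell with it. Tmem176a and Tmem176b, which encode a related pair of membrane proteins, rose by 3.50 ± 0.15 (11.3-fold, adjusted p = 4.10e-12) and 2.80 ± 0.12. The complement component C2 rose by 2.03 ± 0.18, the water channel Aqp1 by 2.16 ± 0.40, and the membrane protease Mme by 1.96 ± 0.33. Other large rises were those of Galnt15, a glycosyltransferase (2.51 ± 0.33), Tktl1, a transketolase-like gene (2.07 ± 0.46), and Lrrc15, a membrane protein of activated fibroblasts (2.04 ± 0.48). Csprs, set aside by hand after its values were seen as 1 of a family of near-identical sequences, rose by 2.35 ± 0.30 (adjusted p = 1.53e-05). Other large falls were those of the adhesion molecule Flrt1 (-3.30 ± 0.36), the carbonyl reductase Cbr2 (-3.03 ± 0.52), the oxytocin receptor Oxtr (-2.93 ± 0.38), the sialic acid hydroxylase Cmah (-2.69 ± 0.27), the transcription factor Creb3l3 (-2.59 ± 0.12) and the long noncoding RNA Miat (-2.55 ± 0.20). With the mean of a gene's probe sets Galnt15 changed by 1.46 and Cmah by -1.51, and both calls held. Within the first and the second run the change was -3.81 and -4.33 for Bcat1, 3.49 and 3.52 for Tmem176a, and -2.59 and -2.37 for Rian.

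Of 19 measured genes for collagen processing and crosslinking, 14 fell and 0 rose in Old ND against Young ND, and adjusted over the list alone 14 fell and 2 rose. The prolyl hydroxylase subunit P4ha2 fell by 1.69 ± 0.14, the crosslinking enzyme Loxl2 by 1.09 ± 0.12, P3h4 of the hydroxylation complex by 1.06 ± 0.08, and the collagen chaperone Serpinh1 by 0.79 ± 0.08. Of 10 fibrillar collagens, 5 fell and 1 rose, both over all genes and adjusted over the list alone. Col5a3 fell by 1.72 ± 0.20, Col5a2 by 1.06 ± 0.10, Col5a1 by 0.98 ± 0.12, Col1a1 by 0.48 ± 0.08 and Col3a1 by 0.27 ± 0.07, while Col27a1 rose. The change of Col3a1 was -1.62 with the mean of its probe sets, and its call ended within the first run (-0.18, adjusted p = 0.223). Col1a1 averaged 13.33 in Young ND, near the highest deposited value of 13.46, where the array scale is compressed. The processing list was shifted down at adjusted p = 2.37e-10, and adjusted p = 0.0732 with an estimated correlation. Its median change was -0.54, and it was -0.62 within the first run and -0.43 within the second. The fibrillar list was shifted down at adjusted p = 0.000982, and adjusted p = 0.389 with an estimated correlation, and within the first run alone its adjusted p was 0.0542.

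Some genes of 4 immune lists rose in Old ND, and none of these lists passed with an estimated correlation. Of 19 measured complement genes, 6 rose and 1 fell, and the same numbers passed adjusted over the list alone. Besides C2, Cfb of the alternative pathway rose by 1.17 ± 0.14 and the protease C1s1 by 1.03 ± 0.08. The list was shifted up at adjusted p = 0.000583, and adjusted p = 0.132 with an estimated correlation. Of 25 genes of antigen presentation and the interferon gamma response, 6 rose and 1 fell (9 and 1 adjusted over the list alone), with a shift at adjusted p = 0.000148, and adjusted p = 0.291 with an estimated correlation. The median change of that list was 0.10 within the first run, where its adjusted p was 0.175, and 0.51 within the second. Of 29 type I interferon genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone), with a shift at adjusted p = 0.0206, and adjusted p = 0.437 with an estimated correlation. The interferon call ended within the first run (adjusted p = 0.95), without Old ND replicate 4 (adjusted p = 0.175) and without Old ND replicate 5 (adjusted p = 0.0888). Of 31 cytokines and chemokines, 5 rose and 1 fell (6 and 1 adjusted over the list alone). Cxcl12, a chemokine that holds lymphocytes and stem cells in their niche, rose by 1.83 ± 0.25 (1.07 with the mean of its probe sets), and Ccl19, which guides cells to lymph nodes, by 0.84 ± 0.13. The chemokine list reached adjusted p = 0.0400, and adjusted p = 0.437 with an estimated correlation. Its call ended with dim genes left out (adjusted p = 0.104 and 0.180), within the first run (adjusted p = 0.157) and without Young ND replicate 3 or Old ND replicate 1, 4 or 5 (adjusted p from 0.0612 to 0.124).

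Of 38 cytosolic ribosomal protein genes, 6 rose and 0 fell in Old ND, and 20 rose adjusted over the list alone, Rps9 by 0.47 ± 0.11. Their median change was 0.22, with 0.18 within the first run and 0.23 within the second, and the list was shifted up at adjusted p = 4.34e-09, and adjusted p = 0.437 with an estimated correlation. Of 25 genes of the unfolded protein response and secretory chaperones, 5 fell and 0 rose, also adjusted over the list alone. Sec61b of the translocation channel fell by 0.83 ± 0.18 and Ppib, a prolyl isomerase that is also on the collagen processing list, by 0.53 ± 0.09. This list was shifted down at adjusted p = 0.000723, and adjusted p = 0.430 with an estimated correlation. Of 39 oxidative phosphorylation genes, 5 fell and 0 rose (9 and 1 adjusted over the list alone), among them Sdhb of complex II (-0.52 ± 0.08) and Cox6a1 of complex IV (-0.48 ± 0.08). The oxidative phosphorylation list was shifted down at adjusted p = 0.000101, and adjusted p = 0.437 with an estimated correlation. Of 27 immediate early genes, 4 rose and 1 fell (the same numbers adjusted over the list alone), with Egr2 up by 0.84 ± 0.13 and Nr4a2 by 0.71 ± 0.15. That list was shifted up at adjusted p = 0.000824, and adjusted p = 0.437 with an estimated correlation. These genes respond within minutes to handling and digestion of tissue.

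Of 16 measured genes of the imprinted growth network, 6 fell and 2 rose, the same numbers adjusted over the list alone. Meg3, Rian and Mirg lie together at 1 locus and Igf2, a fetal growth factor, rose by 1.85 ± 0.18. The list was shifted down at adjusted p = 0.0239, and adjusted p = 0.269 with an estimated correlation, and its call ended with dim genes left out (adjusted p = 0.0537 and 0.0596) and within the second run (adjusted p = 0.0952). Of 14 Hedgehog pathway genes, 3 rose and 0 fell, also adjusted over the list alone, and the list did not pass (adjusted p = 0.0593), though it did without Young ND replicate 1 or 2 or Old ND replicate 2 or 5 (adjusted p from 0.0164 to 0.0317), and under 7 other alternatives, among them the run as a block (adjusted p = 0.0490). They were the receptor Ptch1 (1.53 ± 0.23, and 0.95 with the mean of its probe sets), the transcription factor Gli1 (1.35 ± 0.36) and the coreceptor Gas1 (1.19 ± 0.13). Apoe, a lipid carrier, rose by 1.69 ± 0.15 and Apod by 1.16 ± 0.20, while Pparg, the master regulator of fat cells, did not pass (-0.24 ± 0.09, adjusted p = 0.0850). Pparg did pass with each array centred on its median (adjusted p = 0.0377), with quantile normalization once more (adjusted p = 0.0453) and without Old ND replicate 2 (adjusted p = 0.0438). Among cell cycle inhibitors Cdkn2b rose by 0.64 ± 0.15, and Cdkn2a (-0.07, adjusted p = 0.826) and Cdkn1a (0.02, adjusted p = 0.893) did not pass. Cdkn2b averaged 4.60 in Young ND and 5.24 in Old ND, below the median gene level of 5.88.

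Of the sorting markers, Cd34 averaged 11.01 in Old ND and 11.30 in Young ND (adjusted p = 0.0303, a call that ended without any 1 of 5 arrays, Young ND replicates 3, 4 and 5 and Old ND replicates 1 and 3, with adjusted p from 0.0611 to 0.0910). Pdgfra averaged 6.20 and 5.71 (adjusted p = 0.0699), and it passed with the run as a block (adjusted p = 0.00701), without Old ND replicate 2 (adjusted p = 0.0114) and without Young ND replicate 4 (adjusted p = 0.0443). Of the genes sorted against, Cd24a fell by 1.17 ± 0.21, a call that ended within the first run (-0.80, adjusted p = 0.0675), and Ptprc (3.26 and 3.25), Kit, Pecam1 and Epcam did not pass. None of the 19 cell type lists was shifted, and the smallest adjusted p of those lists was 0.852. The keratin Krt5, chosen after its values were seen, averaged 8.69 in Old ND and 8.85 in Young ND, above the median gene level of 5.88.

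Between Old ND and Young ND 1870 genes changed, 761 up and 1109 down, and 225 of them by at least 2-fold, 109 up and 116 down. With the run as a block the count was 2567, within the first run 1494 and within the second 1049, where more genes rose (572) than fell (477). Of 143 named genes that passed, 141 had the same sign in both runs, and the exceptions were Tgfbi and Rspo1 in the second run. The 143 genes had passed on the arrays of both runs together, which favours the same sign in each.

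Old CR against Old ND asks what 7 months of late restriction did at 18 months of age. The clearest group was the cholesterol synthesis pathway under SREBP2, a transcription factor regulated by sterols. Of its 19 measured genes 9 rose and 0 fell, and 13 rose adjusted over the list alone. Fdps, which makes farnesyl diphosphate, rose by 1.08 ± 0.15 (2.11-fold, adjusted p = 0.00138), the sterol carrier Stard4 by 0.98 ± 0.17 (0.60 with the mean of its probe sets), the sterol dehydrogenase Nsdhl by 0.91 ± 0.12, and Fdft1, the first enzyme committed to sterols, by 0.65 ± 0.11. The median change of the list was 0.48, with 0.44 within the first run, 0.47 within the second and 0.40 with the run as a block. The list passed at adjusted p = 1.01e-12, and adjusted p = 0.0391 with an estimated correlation. With the estimated correlation the call ended without Old ND replicate 1, 2, 4 or 5 or Old CR replicate 1, 3 or 4 (adjusted p from 0.0512 to 0.0888), within the first run (adjusted p = 0.166) and within the second (adjusted p = 0.430). Krt5 (0.01 ± 0.46) and Krt14 (-0.46 ± 0.37), keratinocyte genes that mark other skin cells, did not pass in the same comparison.

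**Figure D1:**
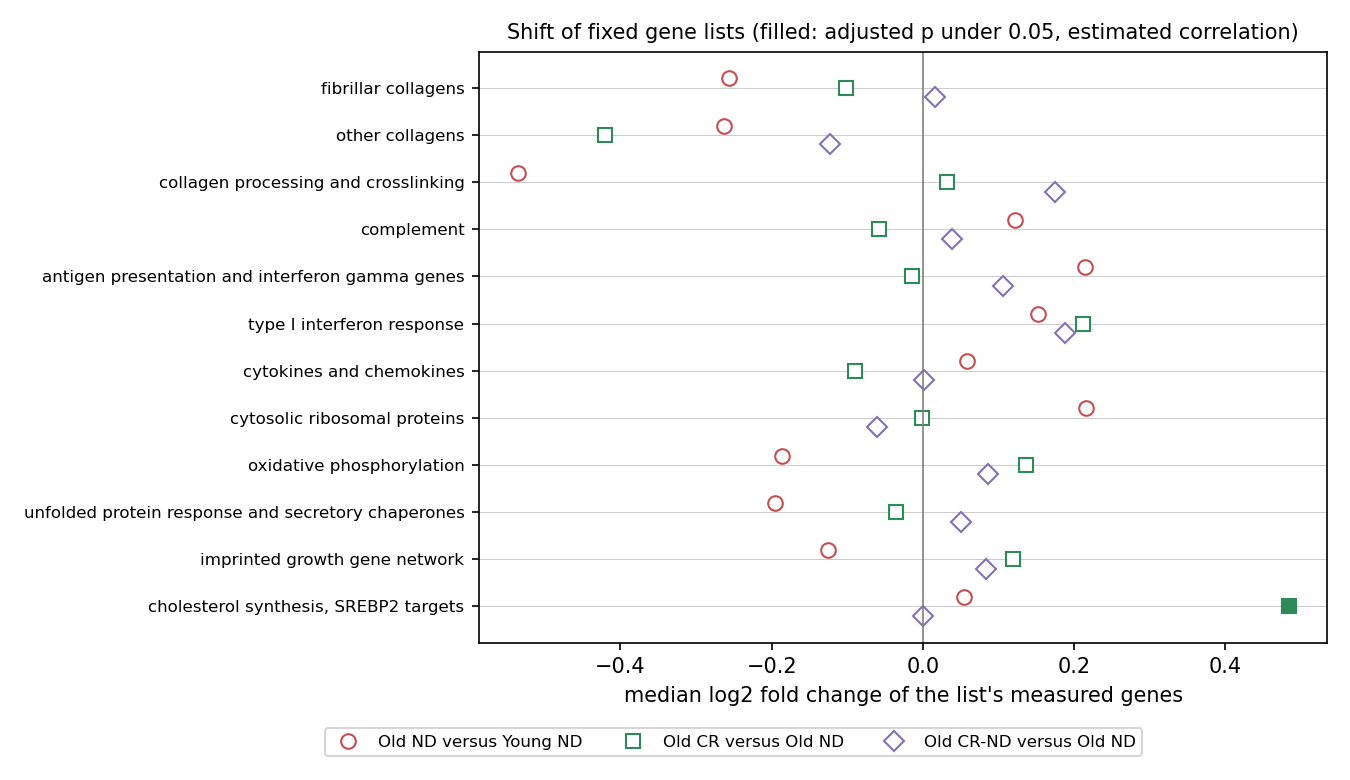
Median log2 fold change (horizontal axis) of the measured genes of 12 gene lists (vertical axis) in Old ND versus Young ND (circles), Old CR versus Old ND (squares) and Old CR-ND versus Old ND (diamonds), with filled symbols for an adjusted p under 0.05 with an estimated correlation. The cholesterol synthesis list stands at 0.48 in Old CR versus Old ND and at 0.00 in Old CR-ND versus Old ND.

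The largest single rise in Old CR was that of Ctla2a, which encodes a cysteine protease inhibitor and was set aside by hand after its values were seen as 1 of a family of near-identical sequences (2.89 ± 0.30, adjusted p = 4.57e-05). Its change was 3.16 within the first run and 1.83 within the second (adjusted p = 0.349). It was followed by Igfbp3, a carrier of insulin-like growth factors (2.38 ± 0.45, adjusted p = 0.00758), and C1qtnf3, a secreted relative of adiponectin (2.27 ± 0.34). Then came Cmah (1.80 ± 0.27), Ddah1, which clears an inhibitor of nitric oxide synthesis (1.72 ± 0.20), Lgr5, a receptor that strengthens Wnt signals (1.64 ± 0.25), the transcription factor Prdm8 (1.59 ± 0.32), Rian (1.50 ± 0.13) and AW551984 (1.41 ± 0.29). With the mean of a gene's probe sets Cmah changed by 0.89, Lgr5 by 1.07 and AW551984 by 0.82, and these calls held. The largest falls were those of Igfbp4, a second carrier of insulin-like growth factors (-2.51 ± 0.45, adjusted p = 0.00489), and Postn, the matrix protein periostin (-2.38 ± 0.51, adjusted p = 0.0157). They were followed by the prohormone protease Cpe (-2.10 ± 0.35), Lrrc15 (-2.07 ± 0.48), the tendon membrane protein Tnmd (-1.95 ± 0.49), the calcification inhibitor Mgp (-1.92 ± 0.25), the neutrophil chemokine Cxcl2 (-1.91 ± 0.32) and the Wnt antagonist Dkk2 (-1.89 ± 0.29). Within the first run the changes were 2.70 for Igfbp3, -3.05 for Igfbp4 and -2.97 for Postn, and within the second run, where Old CR had 1 array, 1.52, -1.20 and -1.60. The call of Lrrc15 ended without Old ND replicate 1 or 3 or Old CR replicate 2, 3 or 4 (adjusted p from 0.0553 to 0.0696). The call of Tnmd ended without any 1 of 8 arrays, all but Old ND replicates 4 and 5 (adjusted p from 0.0513 to 0.104).

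Rian and Meg3, lower in Old ND than in Young ND, were higher in Old CR than in Old ND. Rian lay between 9.39 and 10.24 in the 5 Old CR arrays and between 7.88 and 8.51 in the 5 Old ND arrays. Meg3 rose by 1.34 ± 0.20 (adjusted p = 0.00161), with 1.29 within the first run and 1.02 within the second. Of 16 imprinted growth genes 3 rose and 0 fell (5 and 0 adjusted over the list alone), and the other was Plagl1, a zinc finger regulator of growth (0.55 ± 0.11). Mirg, of the same locus as Rian and Meg3, averaged 5.96 in Old ND and 6.62 in Old CR and did not pass over all genes. The list was shifted up at adjusted p = 0.00449, and adjusted p = 0.132 with an estimated correlation, and its adjusted p within the second run was 0.130.

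**Figure D2:**
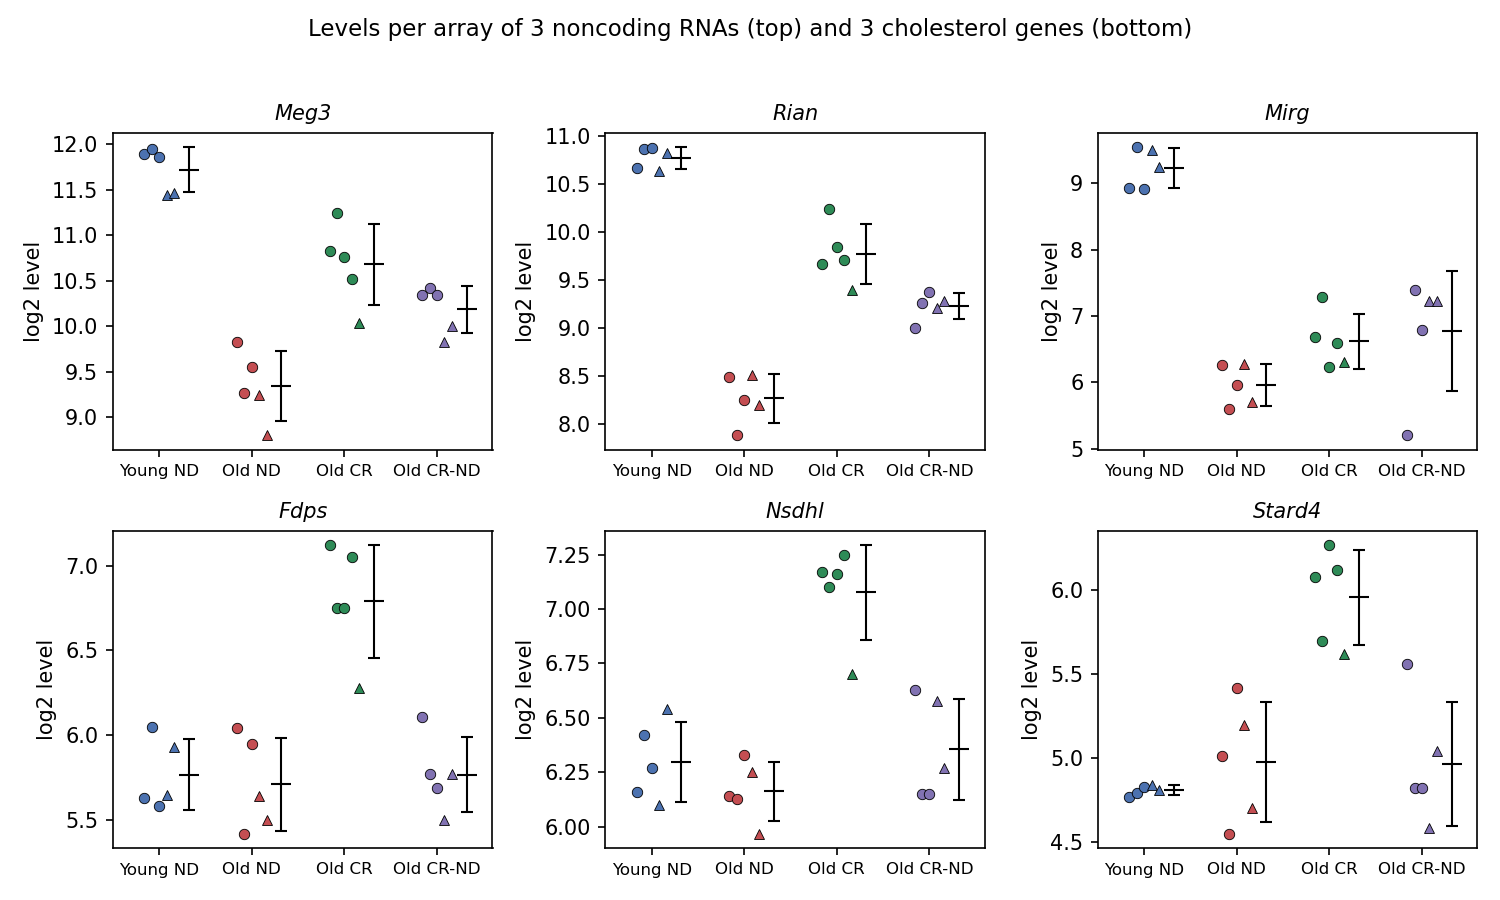
Log2 level (vertical axis) of the noncoding RNAs Meg3, Rian and Mirg (top) and the cholesterol genes Fdps, Nsdhl and Stard4 (bottom) in each of the 20 arrays by group, with circles for the first run of array numbers, triangles for the second, and bars for the mean ± SD of 5 arrays. Fdps lies between 6.28 and 7.12 in Old CR and between 5.42 and 6.04 in Old ND.

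Of 18 measured collagens outside the fibrillar class 3 fell and 0 rose in Old CR against Old ND, and 11 fell adjusted over the list alone. Col15a1 of the basement membrane zone fell by 0.69 ± 0.14, and Col6a3 of the microfibrils by 1.12 ± 0.25, a call that ended without Old ND replicate 1 (adjusted p = 0.0590), Old ND replicate 3 (adjusted p = 0.0523) or Old CR replicate 4 (adjusted p = 0.0651). The median change was -0.42, with -0.50 within the first run and -0.19 within the second, and the list was shifted down at adjusted p = 2.50e-08, and adjusted p = 0.224 with an estimated correlation. Collagen processing and crosslinking genes, which were lower with age, had 0 of 19 that passed either way (2 up and 2 down adjusted over the list alone), and their median of 0.03 and mean of -0.01 differed in sign (adjusted p = 0.881).

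Of 31 cytokines and chemokines 4 fell and 0 rose in Old CR (6 and 1 adjusted over the list alone). The list was shifted down at adjusted p = 0.000175, and adjusted p = 0.166 with an estimated correlation, and its adjusted p within the second run was 0.130. Macrophage and dendritic cell markers moved the same way, with a median change of -0.06 (adjusted p = 0.0116, and adjusted p = 0.512 with an estimated correlation), a call that ended without Old ND replicate 2 (adjusted p = 0.0596) and within the second run (adjusted p = 0.294). Of 29 type I interferon genes 3 rose and 0 fell (5 and 0 adjusted over the list alone), among them Ifit2, an antiviral gene (0.94 ± 0.21), whose call ended without Old CR replicate 4 (adjusted p = 0.0558). The interferon list was shifted up at adjusted p = 0.00449, and adjusted p = 0.536 with an estimated correlation, and its call ended without Old ND replicate 3 (adjusted p = 0.0600), with dim genes left out (adjusted p = 0.0510 and 0.142) and within the second run (adjusted p = 0.496). In the unfolded protein response 3 of 25 genes fell (4 adjusted over the list alone), among them the secreted chaperone Creld2 (-0.80 ± 0.16). That list was shifted down at adjusted p = 0.0110, and adjusted p = 0.536 with an estimated correlation. Its call ended with the run as a block (adjusted p = 0.0509), within each run (adjusted p = 0.113 and 0.130), without Old ND replicate 5 (adjusted p = 0.0722) and without Old CR replicate 1 (adjusted p = 0.0610). None of 39 oxidative phosphorylation genes passed, also adjusted over the list alone, and the median of 0.14 gave adjusted p = 0.000371, and adjusted p = 0.536 with an estimated correlation, a call that ended without Old ND replicate 2 (adjusted p = 0.0756) and within the second run (adjusted p = 0.130).

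Of 12 genes of the dermal papilla and sheath, the hair follicle's fibroblasts, 1 fell in Old CR (5 adjusted over the list alone), the growth factor Fgf10 by 0.79 ± 0.14. The list was shifted down at adjusted p = 0.000553, and adjusted p = 0.231 with an estimated correlation, and its adjusted p within the second run was 0.460. The universal and adventitial fibroblast list was shifted up with a median of 0.24 (adjusted p = 0.0314, and adjusted p = 0.614 with an estimated correlation), and its member Dpp4, a surface protease, rose by 0.92 ± 0.17. The call of that list ended without Old ND replicate 1, 2 or 3 or Old CR replicate 2, 4 or 5 (adjusted p from 0.0542 to 0.142). Of 12 pericyte and smooth muscle markers 1 rose, the potassium channel Kcnj8 by 1.29 ± 0.27, and the list was not shifted (adjusted p = 0.672), with a median of -0.05 and a mean of 0.07.

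Between Old CR and Old ND 409 genes changed, 269 up and 140 down, and 55 by at least 2-fold, of which 24 rose and 31 fell. The count was 711 with the run as a block, 795 within the first run, 1 within the second and 191 with only the 10 arrays compared in the fit, where 34 of 64 named genes passed. Without 1 array it was 238 and 258 (Old ND replicates 1 and 3), and 267, 202, 206 and 201 (Old CR replicates 1, 2, 3 and 4). Of the 64 named genes that passed, 63 had the same sign in both runs, all but Sfrp1. They had passed on the arrays of both runs together, which favours the same sign in each.

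Old CR-ND against Old ND asks what remained 2 months after an earlier restriction had ended. Rian was the 1 gene that passed, higher by 0.96 ± 0.13 in Old CR-ND (1.94-fold, adjusted p = 0.00736), with 1.00 within the first run and 0.89 within the second. Its neighbour Meg3, chosen after its values were seen, was 0.85 ± 0.20 higher and did not pass (adjusted p = 0.378). The lowest p among the genes lower in Old CR-ND belonged to the taurine transporter Slc6a6 (-0.74 ± 0.18), the monooxygenase Fmo2 (-0.93 ± 0.23) and the muscle gene Mustn1 (-0.52 ± 0.13), each at adjusted p = 0.396. Rian missed the threshold with only the 10 arrays compared in the fit (adjusted p = 0.0602), and over its alternatives its adjusted p ranged from 0.00148 to 0.263. At an unadjusted p under 0.05 limma gave 868 genes, where 855 of 17097 would pass by chance. The count was 8 with the run as a block, 22 within the first run and 0 within the second, where 2 arrays stood against 2. It was 5 without Old ND replicate 4 or 5, 4 without Old CR-ND replicate 1, and 2 without Old CR-ND replicate 2 or 3.

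In lists the same comparison showed small shifts. The 29 type I interferon genes had a median of 0.19 and none passed, also adjusted over the list alone (list adjusted p = 2.84e-06, adjusted p = 0.388 with an estimated correlation, and adjusted p = 0.269 within the second run). The 27 immediate early genes had a median of -0.13 and none passed, also adjusted over the list alone (list adjusted p = 4.18e-06, adjusted p = 0.417 with an estimated correlation, and adjusted p = 0.121 within the second run). Collagen processing and crosslinking genes had a median of 0.17, and 3 of 19 were higher adjusted over the list alone (list adjusted p = 8.64e-05, and adjusted p = 0.388 with an estimated correlation). P4ha2 was 0.54 ± 0.14 higher and did not pass over all genes (adjusted p = 0.412). Cholesterol synthesis genes had a median of 0.00 and none passed, also adjusted over the list alone (list adjusted p = 0.619), and Nsdhl was 0.19 ± 0.12 higher (adjusted p = 0.987). Of 33 lists 12 passed with the preset correlation and 0 with an estimated correlation, where fry also gave 0. The 12 fell to 5 without Old CR-ND replicate 4, to 7 without Old ND replicate 3 and to 3 within the second run.

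Old CR-ND against Old CR compares the 2 orders of the diets, at equal age and equal months of restriction. The groups also differ in the diet eaten at collection, so an effect of order cannot be told apart from one of the current diet. The cholesterol genes were lower in Old CR-ND, with 5 of 19 that fell and 0 that rose, and 12 that fell adjusted over the list alone. Fdps fell by 1.02 ± 0.15 (adjusted p = 0.00617), Nsdhl by 0.72 ± 0.12 and Stard4 by 0.99 ± 0.17, a call that ended without Old CR replicate 3 (adjusted p = 0.0532) and within the first run (adjusted p = 0.0912). Within the first and the second run the change was -1.06 and -0.65 for Fdps, -0.86 and -0.28 for Nsdhl and -0.98 and -0.81 for Stard4, and none of them passed within the second (adjusted p from 0.715 to 0.994). The list median was -0.48, with -0.49 within the first run and -0.30 within the second (list adjusted p = 2.62e-15, and adjusted p = 0.0175 with an estimated correlation). The call with an estimated correlation ended within the first run (adjusted p = 0.108) and within the second (adjusted p = 0.441). The 5 Old CR arrays stand in this comparison and in that of Old CR with Old ND. Of 25 genes of the unfolded protein response 2 rose and 0 fell in Old CR-ND (6 and 0 adjusted over the list alone), with a median of 0.18 (list adjusted p = 3.07e-07, and adjusted p = 0.202 with an estimated correlation). Creld2 rose by 0.92 ± 0.15. Of 18 collagens outside the fibrillar class 1 rose (4 adjusted over the list alone), with a median of 0.33 (list adjusted p = 1.69e-05, and adjusted p = 0.306 with an estimated correlation). Lgr5 fell by 1.97 ± 0.25 (adjusted p = 0.000710) and so did Igfbp3 (-2.50 ± 0.45, adjusted p = 0.0142), a call that ended without Old CR replicate 2 or 3 or Old CR-ND replicate 4 or 5 (adjusted p from 0.0517 to 0.0612) and within the first run (-2.26, adjusted p = 0.155). Within the second run, where Old CR had 1 array, the change was -1.44 for Lgr5, 0.465 for Creld2 and -2.47 for Igfbp3. The naming rule did not cover this comparison, and these genes, Nsdhl among them, were chosen for it after their values were seen.

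In the same comparison macrophage and dendritic cell markers had a median of 0.11, and 2 of 20 were higher adjusted over the list alone (list adjusted p = 4.67e-05, adjusted p = 0.0922 with an estimated correlation, and adjusted p = 0.284 within the second run). Keratinocyte and hair follicle markers had a median of 0.11, and 1 of 20 was higher adjusted over the list alone (list adjusted p = 0.0109, and adjusted p = 0.564 with an estimated correlation). That call ended within the first run (adjusted p = 0.335) and without Old CR-ND replicate 4 (adjusted p = 0.0964) or 5 (adjusted p = 0.0887). Of 10 adipocyte progenitor markers 1 rose, and 3 rose adjusted over the list alone (list adjusted p = 0.00540). With an estimated correlation that list reached adjusted p = 0.0494, and the call ended without Old CR replicate 1, 3, 4 or 5 or Old CR-ND replicate 1 or 2 (adjusted p from 0.0720 to 0.114), with the run as a block (adjusted p = 0.0586) and within each run (adjusted p = 0.170 and 0.308). In all 57 genes changed, 21 up and 36 down, with 120 when the run was a block, 235 with array weights and 10 within the first run. Without Old CR replicates 1 to 5 in turn the count was 35, 28, 17, 29 and 110, and without Old CR-ND replicates 2, 4 and 5 it was 24, 29 and 22.

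Against Young ND 2167 genes changed in Old CR, 1216 up and 951 down, and 1203 in Old CR-ND, 550 up and 653 down. With each array centred on its median the numbers were 990 up and 1166 down for Old CR, and 437 up and 905 down for Old CR-ND, so the direction that held more genes turned for Old CR. At 2-fold or more it turned as well, with 123 up and 137 down for Old CR and 73 up and 57 down for Old CR-ND. For Old CR-ND it also turned within the second run (327 up and 294 down) and without Old CR-ND replicate 5 (587 up and 507 down). With the run as a block 2601 and 1754 genes changed, within the first run 1674 and 795, and within the second 576 and 621. The Old CR-ND count was 790 without Old CR-ND replicate 3. Collagen processing and crosslinking genes were lower than in Young ND after both schedules, with 12 of 19 that fell in Old CR (14 adjusted over the list alone) and 10 in Old CR-ND (12 adjusted over the list alone). That list passed at adjusted p = 1.33e-11 in Old CR, where it was the 1 list of 33 that held with an estimated correlation (adjusted p = 0.0468), and at adjusted p = 8.18e-09 in Old CR-ND (adjusted p = 0.0459 with an estimated correlation). In Old CR-ND 11 of 29 type I interferon genes rose (13 adjusted over the list alone; list adjusted p = 1.87e-08, and adjusted p = 0.0494 with an estimated correlation), as did 6 of 19 complement genes (6 adjusted over the list alone; list adjusted p = 1.04e-05, and adjusted p = 0.0449 with an estimated correlation). In Old CR 11 of 19 cholesterol genes rose (14 adjusted over the list alone; list adjusted p = 1.28e-08, and adjusted p = 0.0950 with an estimated correlation). The call with an estimated correlation ended in Old CR without Young ND replicate 1, 2, 3 or 5 or Old CR replicate 1, 2 or 3 (adjusted p from 0.0509 to 0.0782). For the lists named in Old CR-ND it ended without Young ND replicate 1, 3, 4 or 5 or Old CR-ND replicate 4 or 5 (adjusted p from 0.0507 to 0.0965), and for the interferon list also without Old CR-ND replicate 1 (adjusted p = 0.0653) and with the run as a block (adjusted p = 0.0577). Within a run alone each of these calls with an estimated correlation ended (adjusted p from 0.105 to 0.301).

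To ask whether restriction moved old fibroblasts toward the young profile, each array was placed on an age axis that treats the 3 old groups alike, with Young ND at 0 and the mean of the old arrays at 1. Its genes were picked for a difference shared by all old arrays. The axis thus favours genes that restriction did not move and can understate a shift. Old ND scored 1.04 ± 0.06 (SD, n = 5), Old CR 1.02 ± 0.01 and Old CR-ND 0.938 ± 0.087. Old CR differed from Old ND by -0.0152 (exact permutation test, two-sided, p = 0.627). Old CR-ND differed from Old ND by -0.101 (exact permutation p = 0.0794) and from Old CR by -0.0856 (exact permutation p = 0.0714), and over the 3 tests the adjusted exact p was 0.627, 0.119 and 0.119. With more genes on the axis the difference of Old CR-ND from Old CR was larger, and its unadjusted exact p fell under 0.05, as given with the alternatives below. The 252 assignments of 10 arrays allow no exact p below 0.00794. Within the first run the differences were -0.00149, -0.0808 (exact p = 0.40) and -0.0793 (exact p = 0.286), and within the second -0.0268, -0.131 (exact p = 0.333, the smallest possible there) and -0.104. Without Old CR-ND replicate 3 the difference of Old CR-ND from Old ND was -0.138 (exact p = 0.0238) and that from Old CR -0.123 (exact p = 0.00794), and without Old ND replicate 3 that of Old CR from Old ND was -0.0322 (exact p = 0.0317).

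**Figure D3:**
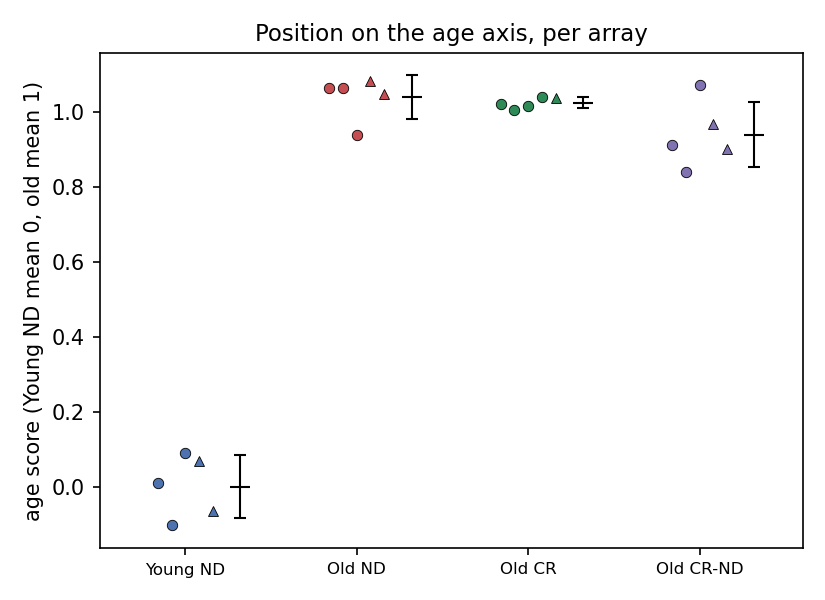
Age score (vertical axis, no unit, Young ND mean 0 and old mean 1) of each of the 20 arrays by group, with circles for the first run of array numbers, triangles for the second, and bars for the mean ± SD of 5 arrays. The 5 Old CR arrays scatter less (SD 0.01) than the Old CR-ND arrays (SD 0.09).

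Across genes, which are not independent replicates, the age effect (Old ND minus Young ND) and the effect of late restriction (Old CR minus Old ND) had Pearson r = -0.294. The shared Old ND arrays alone gave a mean r of -0.479 in data simulated with no effect, with 95% of draws between -0.781 and -0.0497. Those draws lack the spread of the real effects, so the covariance was set beside r, and it was -0.0178 against a mean of -0.00803 with no effect, with 43 of 1000 draws as low. With the Old ND arrays split between the comparisons the mean r was -0.0999, over 20 splits that ranged from -0.288 to 0.0175, and the mean covariance was -0.00688. For Old CR-ND minus Old ND r was -0.50 against -0.491 in data with no effect, and -0.175 with the split. Its covariance was -0.0196 against -0.00830 with no effect, with 36 of 1000 draws as low, and -0.00867 with the split. Of the 140 genes lower in Old CR than in Old ND, 59 had risen with age, where independence would give 6.23, the simulation with no effect 56.6 and the split 32.6. The last 2 values are not counts of called genes. They are overlaps of equally many genes ranked by the moderated test, whether or not these passed. The value with no effect is a mean over 100 draws, and the split leaves fewer Old ND arrays in each comparison. Of the 269 genes higher in Old CR, 67 had fallen with age, against 17.4, 106.5 and 48.3. In the same direction 17 genes had risen with age and were higher in Old CR, against 12.0, 0.890 and 27.4, and 5 had fallen and were lower, against 9.08, 0.810 and 10.9. Among these 67 were Rian, Meg3 and Cmah, and among the 59 were Igfbp4, Lrrc15, Mgp and Cxcl2. The effects of the 2 restriction schedules against Old ND had r = 0.569, against 0.485 with no effect and 0.141 with the split, and their covariance was 0.0160 against 0.00819 with no effect, with 73 of 1000 draws as high.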

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

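The tests of possible sources for the patterns below were chosen after the patterns were seen, and the comparison with other splits of the arrays was planned before the data were examined.

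In 206 groups of 5 arrays, 11 held 1 array that stood far from the other 4, where chance gives about 1 in 20. In Young ND replicate 1 Tmem176b was 7.57 (8.03 to 8.11 in the others), Flrt1 6.94 (9.07 to 9.86), Oxtr 7.85 (9.42 to 9.96) and Apoe 6.88 (7.30 to 7.40). In Old CR, C1qtnf3 was 9.19 in replicate 4 (8.35 to 8.55 in the others), Nsdhl 6.70 in replicate 5 (7.10 to 7.25) and Fgf10 6.16 in replicate 1 (5.81 to 5.90). In Old ND, AW551984 was 6.47 in replicate 4 (4.42 to 4.91 in the others) and Mustn1 7.48 in replicate 1 (6.53 to 6.67). In Old ND replicate 3 the age score was 0.938 (1.05 to 1.08 in the others) and the mean level of the complement genes was 6.68 (6.86 to 6.94).

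Meg3 and Rian were lower in Old ND than in Young ND and higher in Old CR than in Old ND. The run of array numbers as the cause is argued against by the first run alone, where both together were 1.47 ± 0.22 (SE, 7 arrays) higher in Old CR. A lower recovery of long nuclear noncoding RNA is argued against by Malat1, Neat1, Kcnq1ot1, Xist, Airn and Miat, whose mean change from Young ND to Old ND was -0.42 ± 0.06, with -2.55 for Miat and -0.31 to 0.28 for the others. A single Old ND array is argued against by the lowest value with 1 of them left out, 1.35 ± 0.22. An effect of diet on the locus itself may account for the rise, as a hypothesis that was not tested, and so may a change in the kinds of fibroblast sorted. Mirg of the same locus did not pass in Old CR against Old ND.

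The cholesterol synthesis genes were higher in Old CR than in Old ND and in Old CR-ND. The run as the whole cause is argued against by the first run alone, where the 19 genes averaged 0.48 ± 0.12 (SE, 7 arrays) higher in Old CR than in Old ND. Keratinocyte RNA would have to fall with the list in Old CR-ND, and Krt5 and Krt14 together were 0.81 ± 0.25 higher there than in Old CR. A single array is argued against by the lowest value with 1 array left out, 0.43 ± 0.10. Late restriction may raise these genes, a hypothesis found on the same arrays, and the time since the last meal before collection stays open, untested.

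The 8 genes with the largest falls in Old CR, Igfbp4, Postn, Cpe, Lrrc15, Tnmd, Mgp, Cxcl2 and Dkk2, varied together between animals. With group means removed their mean pairwise correlation over 20 arrays was 0.658, against 0.203 at the 95th percentile and 0.420 at the highest of 1000 random sets of equal level, which were not matched on spread. Their mean level had an SD of 0.86 over the Old ND arrays and 0.23 over the Old CR arrays. The run was not removed from these values, and Old CR had 4 arrays in the first run and 1 in the second. The run may therefore carry part of the shared variation, which was not tested. A fibroblast population that differs in share between animals may also carry these genes, a source the data do not name. Pericytes and smooth muscle cells are argued against by their 4 markers above the median level, which were 0.36 ± 0.10 higher in Old CR (0.05 ± 0.11 without Kcnj8, and 0.07 ± 0.03 over all 12 markers). The run as the cause of the fall is argued against by the first run alone, where the 8 genes changed by -2.56 ± 0.44. Diet stays open beside the place of skin sampled and the gating of the sort, neither of which was tested.

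Each gene count and list count was set against 100 of the 126 splits of its 10 arrays into 5 and 5. For genes, in 5 comparisons 1 drawn split, the real one, gave as many. They were Old ND against Young ND (1870, highest other 500), Old CR against Old ND (409 and 20), Old CR-ND against Old CR (57 and 55), Old CR against Young ND (2167 and 74) and Old CR-ND against Young ND (1203 and 178). In Old CR-ND against Old CR the margin was narrow and not every split was drawn, so chance is not firmly excluded there. In the others of these the wide margin argues against chance, though not every split was drawn and the share was not adjusted over the comparisons. For Old CR-ND against Old ND chance cannot be excluded, since 11 splits gave at least its 1 gene and the highest other gave 447. In each comparison the highest other split was among those that followed the run of array numbers most closely, but the rest of these gave 18 genes or fewer. A split of Old ND and Young ND that followed the run less closely gave 408. The 447 genes against 1 point to a structure of the samples. No split into 5 and 5 can match the run fully here, since each group had 3 arrays in the first run and 2 in the second. The closest splits each put 1 array of the first run with those of the second. The other 4 splits that followed the run as closely gave 0, so these counts cannot tell whether the run gives the 447. On principal component 2, however, Old CR-ND replicate 3 of the first run lay at -9.86, beside the second run (-18.6 to -10.5). The other arrays of the first run lay at 0.693 to 19.3. Whether that array was the one placed with the second run in the split that gave 447 was not recorded. With the run as a block the counts were 2567 (Old ND against Young ND), 8 (Old CR-ND against Old ND), 120 (Old CR-ND against Old CR) and 1754 (Old CR-ND against Young ND). For lists, 2 splits, the real one included, gave as many as the real 14 for Old CR-ND against Young ND, and the highest other gave 14. The share of splits was low, but it was not adjusted over the comparisons. The real count fell to 11 without Old CR-ND replicate 5, so chance is not firmly excluded there. It cannot be excluded for Old ND against Young ND (9 splits as high as 13, highest other 20), Old CR against Old ND (34 splits, 10 and 18), Old CR-ND against Old ND (23 splits, 12 and 17), Old CR-ND against Old CR (13 splits, 12 and 14) and Old CR against Young ND (18 splits, 12 and 14).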

How the results depend on the processing

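The alternatives in this part were chosen before the data were examined, except those of the last sentences. Fewer arrays, another threshold and more tests move counts by construction, and for the other moved values the cause was not tested.

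Genes changed in Old CR-ND against Old ND (1) became 2 with the dimmest genes left out, 3 with more of the dim genes left out, 11 with every probe set, 2 with quantile normalization, 0 with only the 2 groups compared, 8 with the run as a block, 22 in the first run, 0 in the second and 0 at 2-fold or more. Beside these counts of 0, limma gave 868 genes at an unadjusted p under 0.05 with all arrays. With every probe set the counts were 3078 for Old ND against Young ND, 615 for Old CR against Old ND, 3538 for Old CR against Young ND and 1891 for Old CR-ND against Young ND. In Old CR against Old ND (409) only the 2 groups compared gave 191, the run as a block 711, the first run 795 and the second 1. In Old CR-ND against Old CR (57) array weights gave 235, the block 120, the first run 10 and the second 1. The first run gave 795 for Old CR-ND against Young ND, and the second gave 1049, 576 and 621 for Old ND, Old CR and Old CR-ND against Young ND. At adjusted p under 0.01 the counts were 1029, 1225 and 593 against Young ND in the same order, 98 for Old CR against Old ND and 19 for Old CR-ND against Old CR, and at 2-fold or more they were 225, 260, 130, 55 and 8.

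Of 33 lists, an estimated correlation left 0 (Old ND against Young ND, 13 with the preset one), 1 (Old CR against Old ND, 10), 0 (Old CR-ND against Old ND, 12), 1 (Old CR-ND against Old CR, 12), 1 (Old CR against Young ND, 12) and 5 (Old CR-ND against Young ND, 14). Fry gave 2, 0 and 1 for the comparisons of Old CR and Old CR-ND with Old ND and of both with each other. The first run gave 8 lists for Old ND against Young ND, and the second 5 for Old CR and 3 for Old CR-ND against Old ND. The age score difference of Old CR-ND from Old CR was -0.126 with 1000 genes and -0.148 with all genes (exact p = 0.0397 for each), and that from Old ND was -0.112 with arrays centred on their medians (exact p = 0.0476). The correlation of the age effect with the effect of Old CR was -0.0999 over genes that differed between all old and young mice, -0.0999 with the Old ND arrays split, and -0.0315 with both, and that for Old CR-ND was -0.175 with the split.

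With 1 array left out the gene counts ranged from 1454 to 1847 (Old ND against Young ND), 201 to 498 (Old CR against Old ND), 1 to 5 (Old CR-ND against Old ND), 17 to 110 (Old CR-ND against Old CR), 1719 to 2171 (Old CR against Young ND) and 790 to 1187 (Old CR-ND against Young ND). The list counts ranged in the same order from 11 to 16, 9 to 14, 5 to 14, 8 to 12, 11 to 14 and 11 to 14. The age score difference ranged from -0.0322 to -0.00619 for Old CR against Old ND, -0.138 to -0.0838 for Old CR-ND against Old ND and -0.123 to -0.0657 for Old CR-ND against Old CR.

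Over the named genes and alternatives 4908 values kept their side of the threshold, 638 lost it, 18 gained it and 3 turned. Those 3, in the second run, were Tgfbi (0.12) and Rspo1 (0.00) in Old ND against Young ND and Sfrp1 (-0.005) in Old CR against Old ND. With the run as a block 143 of 143, 64 of 64 and 1 of 1 named genes kept their call in the 3 comparisons with Old ND, against 109, 34 and 0 with only the 2 groups compared. Signal near the background limits genes sorted against, such as Ptprc at 3.26 beside a lowest value of 2.71. Arrays left out and runs for the genes of Old CR-ND against Old CR, for Ctla2a and Csprs, for cell type lists and for calls with an estimated correlation were added after the data were seen. Of these values 349 kept their side of the threshold, 91 lost it, 1 gained it and 1 turned, the universal and adventitial fibroblast list in Old CR against Old ND (median -0.015 in the second run, adjusted p = 0.801).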

Other observations

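No tests beyond those of the report were run for this part, and the genes below come from the same naming rule unless stated.

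With age on a normal diet, genes of several other pathways changed in single members. Of 30 Wnt pathway genes 3 rose and 3 fell (3 and 4 adjusted over the list alone; list adjusted p = 0.633). Lgr5, a receptor that strengthens Wnt signals, rose by 1.64 ± 0.25 (0.97 with the mean of its probe sets), and Notum, an enzyme that inactivates Wnt proteins, fell by 0.43 ± 0.08. Notum was among the dim genes that the filters on level left out. Of 29 TGF-beta and BMP genes 5 rose and 0 fell (6 and 1 adjusted over the list alone), with Ccn2, a matrix-associated growth factor target, up by 0.77 ± 0.13. That list was shifted up at adjusted p = 0.0124, and adjusted p = 0.437 with an estimated correlation, and its call ended without Old ND replicate 1 (adjusted p = 0.0966) and within the first run (adjusted p = 0.0523). Of 22 antioxidant genes 2 rose and 3 fell (4 and 3 adjusted over the list alone; list adjusted p = 0.539), among them the oxidase Aox1 (0.99 ± 0.11), the glutathione transferase Gstt1 (0.85 ± 0.12) and the secreted peroxidase Gpx3 (-1.77 ± 0.42). The crosslinking enzyme Tgm2 fell by 2.47 ± 0.43, and the matrix protease Mmp11 rose by 1.51 ± 0.20. Of 17 clock genes 2 rose and 2 fell (4 and 4 adjusted over the list alone; list adjusted p = 0.819). Hlf (0.69 ± 0.14) and Tef (0.49 ± 0.09) rose and Clock fell by 0.63 ± 0.08 (0.42 with the mean of its probe sets), and the hour of collection was not analysed here.

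In Old CR against Old ND the lysosomal enzyme Gla rose by 0.66 ± 0.12 (adjusted p = 0.0542 with the mean of its probe sets, which ended the call), 1 of 2 that rose among 22 autophagy and lysosome genes (3 adjusted over the list alone; list adjusted p = 0.0627, which passed within the first run and without Old ND replicate 4 or 5 or Old CR replicate 1, with adjusted p from 0.00793 to 0.0440). Decr1, an enzyme of fatty acid oxidation, rose by 0.36 ± 0.06, a call that ended with the mean of its probe sets (0.16, adjusted p = 0.145), and Ccn5, a Wnt target, fell by 0.96 ± 0.16. The adhesion molecule Vcam1 fell by 1.28 ± 0.28, a call that ended without Old CR replicate 1 or 4 or Old ND replicate 1 (adjusted p from 0.0508 to 0.0635).

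Old CR-ND replicate 3, singled out after its values were seen, lay near the Old CR arrays in Postn and Igfbp3 and away from them in others. Its Postn level was 7.14, where Old CR ranged from 6.85 to 7.64 and the other Old CR-ND arrays from 8.74 to 10.14. Its Igfbp3 level was 8.62, where Old CR ranged from 8.55 to 9.86 and the other Old CR-ND arrays from 5.94 to 6.93. Its mean level of the cholesterol synthesis genes was 6.16, the lowest of the Old CR-ND arrays, where Old CR ranged from 6.54 to 6.87. Its Lgr5 level was 7.06, where Old CR ranged from 8.21 to 9.58. Old ND replicate 2, also singled out afterwards, had the lowest array weight, 0.326, where the others ranged from 0.605 to 1.91.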
